A study of Mus musculus with 20 samples.

How the data were processed

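Hippocampal RNA from male wild-type and Fkbp5 knockout mice (strain label C57BL/6J, 12 weeks of age) was sequenced 7 days after 1 injection of saline or of 3 mg/kg LPS, with 5 libraries in each of 4 groups. Per the labels, the authors extracted RNA with the RNeasy Plus Mini kit, made libraries from 1 µg of total RNA with NEBNext Ultra reagents, trimmed reads with Trimmomatic, inspected them with FastQC and MultiQC and counted them with featureCounts against mm10. The labels do not state the aligner, the annotation release, the strand setting or the handling of reads that map to several places. The deposited values are raw counts per gene, whole numbers that the authors had neither normalized nor filtered, for 55536 Ensembl genes in 20 libraries. All (100%) of the gene identifiers matched the GENCODE M21 annotation of GRCm38, from which symbols, positions and biotypes were taken. No sample column was left unused.

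Total counts per library were 16652992 to 27230202, and 33626 genes had a count in some library. A count of 0 was read as an upper limit of 3 counts over the group's total. Levels are given as counts scaled to a common library total (CPM, edgeR's cpm with the TMM factors), as mean and SD over the 5 libraries of a group.

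Differences were tested in edgeR 4.0.16 under R 4.3.3 with TMM normalization, the default expression filter by group (filterByExpr, 16419 genes kept), a quasi-likelihood fit with robust dispersion and the quasi-likelihood F test. All 20 libraries entered 1 fit without further terms. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 7 comparisons were LPS against saline in wild-type, the same in knockout, knockout against wild-type after saline, the same after LPS, the interaction of genotype and treatment, and both main effects averaged over the other factor. A fold against a group without any count is a lower bound from the 3-count limit over the group.

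Gene lists for cell types, neighbouring tissues, inflammation and cell functions were fixed before the data were examined. Of 40 lists, 38 had at least 4 tested members; the lymphocyte list and the neutrophil and monocyte list did not. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 38 lists in each comparison, and again with the correlation estimated from the data. Members were also adjusted over the list alone.

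The genes named in the report were chosen by a rule fixed before the data were examined. In each of the 5 main comparisons it took Fkbp5, the 10 genes with the smallest p that rose and the 10 that fell past the threshold (without predicted genes and clone names), and up to 4 members with the smallest p of each list that was called or had several members past the threshold. Where fewer than 5 genes were called it took the 5 with the smallest p as values. A set of genes of inflammation and the glucocorticoid response was named in any case. Genes within 20 Mb of Fkbp5 are named with that position, because DNA of the line the knockout was made in can remain there.

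The alternatives planned beforehand were DESeq2's size factors in edgeR, DESeq2 1.42.0 (Wald test), limma-voom with quality weights, no filter on low counts, a stricter filter (at least 1 CPM in 5 libraries), the replicate number as a block, 1 surrogate variable (sva 3.50.0), a fit of only the 2 groups compared, the comparisons without genes within 20 Mb of Fkbp5, a window of 5 Mb, the estimated camera correlation, and leaving out each library in turn. Added after the data were seen were a term for the library set, each library set alone, the fit without the 3 libraries with the most thalamus RNA, with and without the replicate block, and the replicate block together with the estimated correlation. The labels do not say what the replicate numbers stand for. After removal of the group means, the 30 pairs of libraries with the same number correlated at 0.264 to 0.854 (median 0.462), pairs of another number in the same set at 0.191 to 0.672 (median 0.45) and pairs across the sets at -0.705 to -0.149. After removal of the mean of each group within each set, pairs with the same number had a median of 0.214 in replicates 1 and 2 (-0.265 to 0.63; pairs of another number -0.214) and 0.0156 in replicates 3 to 5 (-0.122 to 0.157; pairs of another number -0.00975). These correlations separated the library sets, and 11 of 20 libraries correlated best with a library of their own number. In replicates 1 and 2 the values of opposite sign follow from centring 2 libraries per group. Pairing by number was thus not established, and the block remained an alternative, as planned.

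Enrichment by position, biotype and near-identical copy used the 1-sided Fisher exact test against the tested genes. Copies were found by aligning transcripts with blast 2.17.0 (at least 95% identity over at least 30% of the length). Overlapping genes were read from the annotation. Each count was compared with 100 other splits of the libraries into groups of the same sizes, and with splits that exchange groups within a replicate number. Tables were made in R and in python 3.11.15, and plots in matplotlib 3.10.9.

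The fit was tested on simulated data in which 200 genes were changed by known folds in counts with the spread of these libraries. Genes changed 3-fold were recovered in 66.7% of cases for the interaction and in 68.2% to 92.4% for the other comparisons, and genes changed 1.5-fold in 7.46% and in 22.4% to 53.7%. Between 0 and 2 unchanged genes were called in this fit without further terms. With the replicate block they were 11 of 186 called genes for LPS in wild-type, 14 of 180 for knockout after saline and 5 of 182 for knockout after LPS.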

Results

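RNA sequencing measured transcript levels in the hippocampus of male mice aged 12 weeks, which were wild-type or carried a knockout of Fkbp5. FKBP5 is a co-chaperone of HSP90 that lowers the activity of the glucocorticoid receptor. The animals had received 1 intraperitoneal injection of saline or of 3 mg/kg lipopolysaccharide (LPS, a bacterial cell wall component that triggers inflammation), and tissue was collected on day 7. The 4 groups held 5 libraries each. Total counts per library ran from 16652992 to 27230202, with a median of 19642484. Totals were 18155379 to 20159616 in wild-type saline, 16652992 to 21810400 in wild-type LPS, 16746944 to 25840538 in knockout saline and 17503531 to 27230202 in knockout LPS. A count of 0 over the whole wild-type saline group allowed a level of up to 0.0314 CPM (counts scaled to a common library total). Such limits cover counting error only. The p-values of single genes measure the spread between these libraries. Those of gene lists (camera) compare the genes of a list with the other genes tested, and those of the Fisher exact tests rest on counts of genes. The labels do not state whether each replicate was a separate animal.

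The libraries fell into a pair of sets that the groups did not explain. Replicates 1 and 2 of every group formed one set and replicates 3 to 5 the other, and principal component 1, with 52.9% of the variance, separated them. Mitochondrially encoded genes took 5.05% ± 0.37 (SD, n = 8) of counts in the first set and 9.60% ± 0.88 (n = 12) in the second. The number of genes detected was 24313 ± 655 (SD) and 21641.7 ± 362. Between the sets 10565 of 16419 tested genes differed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Both sets were present in every group in the same numbers, so counts within each set, and values within each set for the leading genes and lists, are given beside the pooled ones.

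**Figure D1:**
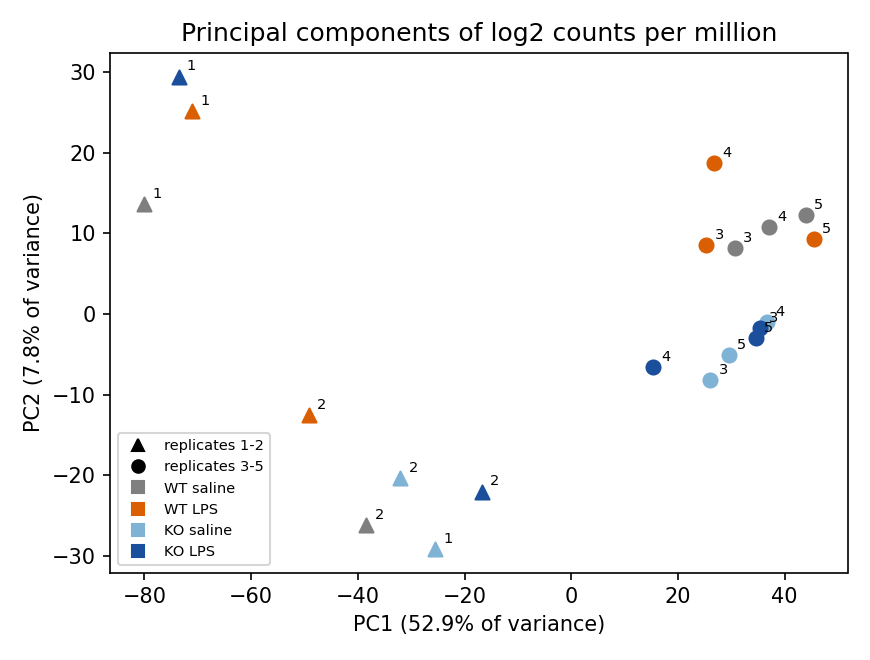
Principal components 1 and 2 of log2 CPM in the 20 libraries, with the share of variance (%) on each axis; each point is 1 library, coloured by group and numbered by replicate. Replicates 1 and 2 of all 4 groups lie on one side of component 1 (52.9% of the variance) and replicates 3 to 5 on the other.

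Fkbp5 (ENSMUSG00000024222, mm10 chromosome 17, 28399094 to 28517527) was lower in every knockout library than in any wild-type library, with transcript remaining. It stood at 63.1 ± 6.71 CPM (SD, n = 5) in wild-type saline, 66.2 ± 4.87 in wild-type LPS, 30.7 ± 4.46 in knockout saline and 29.5 ± 4.06 in knockout LPS. The 10 wild-type libraries ran from 56.7 to 73.4 CPM and the 10 knockout libraries from 25.1 to 35.99, so the genotypes did not overlap. The knockout level was 48.6% of wild-type after saline and 44.6% after LPS. The log2 fold change was -1.04 ± 0.11 (SE) after saline (edgeR adjusted p = 2.79e-05) and -1.17 ± 0.11 after LPS (adjusted p = 7.05e-06). Over both treatments it was -1.10 ± 0.08 (adjusted p = 3.63e-08), with -1.06 in replicates 1 and 2 alone (adjusted p = 0.12) and -1.13 in replicates 3 to 5 alone (adjusted p = 1.4e-08). LPS left the Fkbp5 level within its spread, with log2 fold changes of 0.07 in wild-type and -0.06 in knockout (interaction -0.13 ± 0.16, edgeR adjusted p = 1). Gene counts cannot show whether the remaining transcript lacks an exon.

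**Figure D2:**
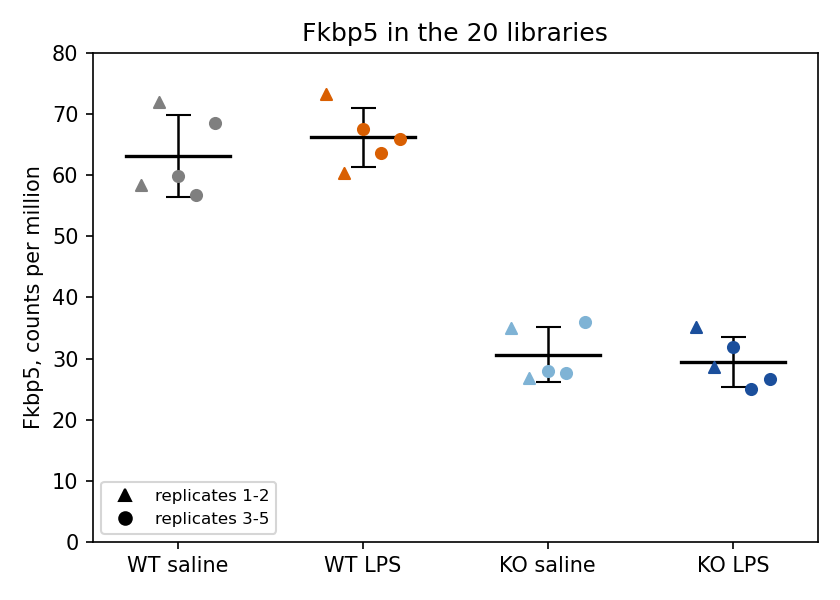
Fkbp5 level (CPM, linear axis from 0) in each of the 20 libraries by group; points are libraries and lines are the group mean with its SD (n = 5). The 10 knockout libraries lie between 25.1 and 35.99 CPM and the 10 wild-type libraries between 56.7 and 73.4.

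The comparison of LPS with saline in wild-type mice asked which transcripts still differed 7 days after the injection. Lag3, an immune checkpoint receptor, stood at 5.74 ± 0.45 CPM (SD, n = 5) after saline and 11.4 ± 1.38 after LPS, a log2 fold change of 0.99 ± 0.17. Saa3, an acute-phase serum amyloid gene, had no count in any saline library and 143 counts over the 5 LPS libraries, at least 46.7-fold higher against a floor of 3 counts over the group. Both genes were higher in 5 of 5 LPS libraries than in every saline library. Lyz2, the lysozyme of myeloid cells, stood at 3.81 ± 0.81 and 10.6 ± 5.51 CPM, and Lcn2, the iron-binding lipocalin of reactive astrocytes, at 0.0883 and 0.671 CPM. No gene passed edgeR at adjusted p under 0.05 (Lag3 0.24, Saa3 0.523, Lcn2 0.844, Lyz2 1). At an unadjusted p under 0.05 there were 340 genes, DESeq2 called 2 and limma-voom 3, and edgeR with the replicate number as a block called 3 (Lag3, Saa3 and Lyz2, adjusted p = 0.00787 each). The sets alone gave 0 and 0 genes.

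At the level of gene lists, 21 of 38 differed after LPS in wild-type, 19 of them higher (camera with a preset correlation of 0.01). With an estimated correlation 6 lists were called, and with the replicate block and an estimated correlation 0 (smallest adjusted p = 0.0631). In the sets alone 24 and 20 differed, with 18 and 15 of the 21 among them, and without the 3 libraries described next 13. The class I antigen presentation list had the smallest p, with 13 of 14 members above 0 and a median log2 fold change of 0.25 (adjusted p = 6.97e-13, and 0.019 with an estimated correlation). Its members H2-D1 and H2-K1, which present peptides to cytotoxic T cells, went from 34.9 to 54.0 CPM and from 28.4 to 40.7 CPM. Both lie within 20 Mb of Fkbp5, as do 11 of the 14 members. Within the sets its adjusted p was 2.37e-12 and 0.000103. All 14 complement genes were above 0, with a median of 0.29 (adjusted p = 2.06e-08, and 0.0418 with an estimated correlation); C3 had 0.72 and C1qa 0.27. The pan-reactive astrocyte list, with Vim and Lcn2, had a median of 0.31 (adjusted p = 9.06e-08, and 0.019 with an estimated correlation). The LPS-type reactive astrocyte list had 0.25 (3.56e-08 and 0.044), and the NF-kB and cytokine list, with Cxcl16 at 0.90 and Icam1 at 0.84, had 0.15 (1.16e-05 and 0.011). H2-D1 belongs to both the LPS-type astrocyte list and the class I list, so the calls of those lists are not fully separate. Within replicates 3 to 5 the LPS-type astrocyte list had adjusted p = 0.128 and the complement list 0.0482.

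Markers of tissue outside the hippocampus moved with the same contrast. All 10 thalamus markers were above 0 after LPS in wild-type, with a median of 0.46 (adjusted p = 3.45e-08, and 0.0259 with an estimated correlation); Slc17a6, a vesicular glutamate transporter, had 1.24 and Tcf7l2 0.65. The thalamus list scored 1.12 in wild-type LPS replicate 1, 0.942 in wild-type LPS replicate 4 and 0.869 in knockout LPS replicate 1, against -0.557 to 0.264 in the other 17 libraries. Without those 3 libraries the thalamus list had adjusted p = 0.0667, class I genes 4.64e-06, complement genes 4.75e-06, pan-reactive astrocyte genes 0.00014 and LPS-type astrocyte genes 0.00471. All 13 meningeal fibroblast markers were also above 0, with a median of 0.41 (adjusted p = 1.24e-06, and 0.18 with an estimated correlation). The meningeal call ended without those 3 libraries (adjusted p = 0.956) and in replicates 3 to 5 alone (0.977). Class II genes, with a median of 0.56 (adjusted p = 0.0032, and 0.121 with an estimated correlation), had 0.393 without the 3 libraries. The calls of 5 lists named next also ended without them, namely extracellular matrix (0.172), striatum (0.386), mural cells (0.0622), HSP90 chaperones (0.532) and mitochondrially encoded genes (0.81). These losses are those of the fit without further terms. With the replicate block added, 20 lists were called without the 3 libraries, 18 of the 21 among them, so most of the calls that ended returned.

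Further lists were higher in wild-type after LPS with calls that did not hold with an estimated correlation. They were interferon response (21 of 23 members above 0, median 0.33, adjusted p = 1.47e-08, and 0.0937 estimated), in which Irf7 had 0.80 and Parp14 0.67, and myelin (15 of 15, median 0.21, 1.47e-08 and 0.108). Endothelial markers had 5.25e-08 (0.118 estimated), activated microglia 8.77e-06 (0.18), extracellular matrix 5.03e-05 (0.118), blood 0.00147 (0.186), circadian 0.00202 (0.108), striatum 0.00519 (0.108), homeostatic astrocytes 0.00573 (0.439), homeostatic microglia 0.0163 (0.464) and mural cells 0.0169 (0.386). Lower lists were HSP90 and its co-chaperones (median -0.08, adjusted p = 0.0106, and 0.463 estimated) and the mitochondrially encoded genes (median -0.12, 0.0112 and 0.464). Over all genes tested, 0 of the 38 lists had a member past the threshold (edgeR). Adjusted over the list alone, 7 lists had one.

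In knockout mice LPS raised 1 gene, Lag3 (ENSMUSG00000030124, chromosome 6, 124904361 to 124911705), from 6.42 ± 1.03 to 14.5 ± 4.15 CPM (SD, n = 5), a log2 fold change of 1.18 ± 0.17 (edgeR adjusted p = 0.0216). Every LPS library was above every saline library. Saa3 again had no count after saline and 204 counts after LPS, at least 66.0-fold higher (adjusted p = 0.122). Tlr2, the receptor for bacterial lipoproteins, stood at 0.69 and 2.24 CPM (log2 fold change 1.70 ± 0.32, adjusted p = 0.122), and Unc93b1, which escorts endosomal Toll-like receptors, at 12.8 ± 1.49 and 19.2 ± 2.26 CPM (0.59 ± 0.11, adjusted p = 0.122). At an unadjusted p under 0.05 there were 287 genes, DESeq2 called 7 and limma-voom 2. With the replicate block 5 were called, namely Tlr2, Csf3r, Lag3, Saa3 and Unc93b1. The Lag3 call was lost in replicates 1 and 2 alone (adjusted p = 0.888) and without any 1 of 8 of the 10 libraries (0.0513 to 0.142), and was kept without knockout saline replicate 2 or knockout LPS replicate 1. The sets alone gave 0 and 3 genes.

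Class I antigen presentation was again the list with the smallest p in knockout, with 12 of 14 members above 0 and a median of 0.35 (adjusted p = 1.96e-15, and 0.0232 with an estimated correlation). Within the sets its adjusted p was 5.85e-13 and 3.19e-05. Adjusted over the list alone, 5 of its members passed (H2-K1, H2-D1, H2-Q6, H2-Q7 and B2m), against 0 over all genes tested; class I genes are close relatives and can share reads. Activated microglia genes had 16 of 18 members above 0, Itgax with 1.35 and Cd52 with 1.09 among them, and a median of 0.17 (adjusted p = 5.39e-07, and 0.311 with an estimated correlation). Complement genes had a median of 0.16 (2.77e-04, and 0.311 estimated), with C3 at 1.25 and C3ar1 at 0.75. Lower in knockout after LPS were all 13 meningeal markers (median -0.38, adjusted p = 4.2e-05, and 0.484 estimated), border macrophages with Lyve1 at -0.80 and Mrc1 at -0.53 (0.00208, and 0.484 estimated) and dentate granule cells (median -0.20, 3.05e-04, and 0.345 estimated). In replicates 1 and 2 alone the meningeal list had adjusted p = 0.753. Its mean log2 level relative to all libraries was 0.72 and 0.858 in knockout saline replicates 4 and 5. It was -0.696 to 0.239 in the other knockout saline libraries and -0.628 to 0.194 in the knockout LPS libraries. Border macrophages had 0.81 and 0.675 in the same replicates 4 and 5. These saline libraries also enter knockout against wild-type after saline and the interaction, so the results on these lists are not independent.

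In all, 17 lists differed in knockout, 10 higher and 7 lower, and 19 and 11 in the sets alone, with 13 and 7 of the 17 among them. The count was 10 without knockout saline replicate 1 and 11 without knockout saline replicate 2. With an estimated correlation 1 list was called, and with the replicate block and an estimated correlation 0 (smallest adjusted p = 0.169). The rest had small shifts, and none of their calls held with an estimated correlation. Higher were homeostatic microglia (adjusted p = 0.00706, and 0.586 estimated), LPS-type astrocytes (0.0083 and 0.484), myelin (0.0237 and 0.586), NF-kB and cytokines (0.0237 and 0.246), ribosomal proteins (0.0426 and 0.779), pan-reactive astrocytes (0.0447 and 0.501) and interferon response (0.0447 and 0.586). Lower were HSP90 chaperones (0.00885 and 0.586), glutamate synapse (0.0155 and 0.541), neurogenesis (0.0332 and 0.246) and homeostatic astrocytes (0.0426 and 0.628). With the replicate block the calls ended for NF-kB and cytokines (0.0561), neurogenesis (0.0587), interferon response (0.0587) and pan-reactive astrocytes (0.0774). Without the 3 libraries with the most thalamus RNA 11 of the 17 calls were kept; they ended for homeostatic astrocytes (0.642), pan-reactive astrocytes (0.116), interferon response (0.667), HSP90 chaperones (0.791), glutamate synapse (0.665) and neurogenesis (0.0565). Adjusted over the list alone, 6 of the 38 lists had a member past the threshold, against 0 over all genes tested (edgeR).

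Over both genotypes 7 genes rose after LPS and none fell (445 at an unadjusted p under 0.05, 23 by DESeq2 and 17 by limma-voom, 27 with the replicate block). The count was 4 without any 1 of wild-type saline replicates 2, 3 and 4, wild-type LPS replicates 3, 4 and 5, knockout saline replicates 3 and 4, and knockout LPS replicate 1. The genes were Lag3 (1.08 ± 0.12, edgeR adjusted p = 4.47e-04), Saa3 (0.0126), H2-D1 (0.70 ± 0.11, 0.0128), Neurl3 (0.0128), Unc93b1 (0.0267), Tlr2 (1.28, 0.0377) and H2-Q6 (0.0377). H2-D1 was above every saline library of its genotype in 10 of 10 LPS libraries. With the replicate block Lyz2 (adjusted p = 0.00078), H2-K1 and Csf3r (0.00639 each), Lcn2 (0.0118), Cd52 (0.0252) and B2m (0.0285) were among those called. Without the 3 libraries with the most thalamus RNA, Lag3 alone stayed past the threshold (adjusted p = 3.84e-05). Replicates 1 and 2 alone gave 0 genes (418 at an unadjusted p under 0.05) and replicates 3 to 5 alone 5, with Lag3 (1.26e-05) and Saa3 (0.0045) among them and 0.0617 to 0.426 for the other 5 of the 7.

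**Figure D3:**
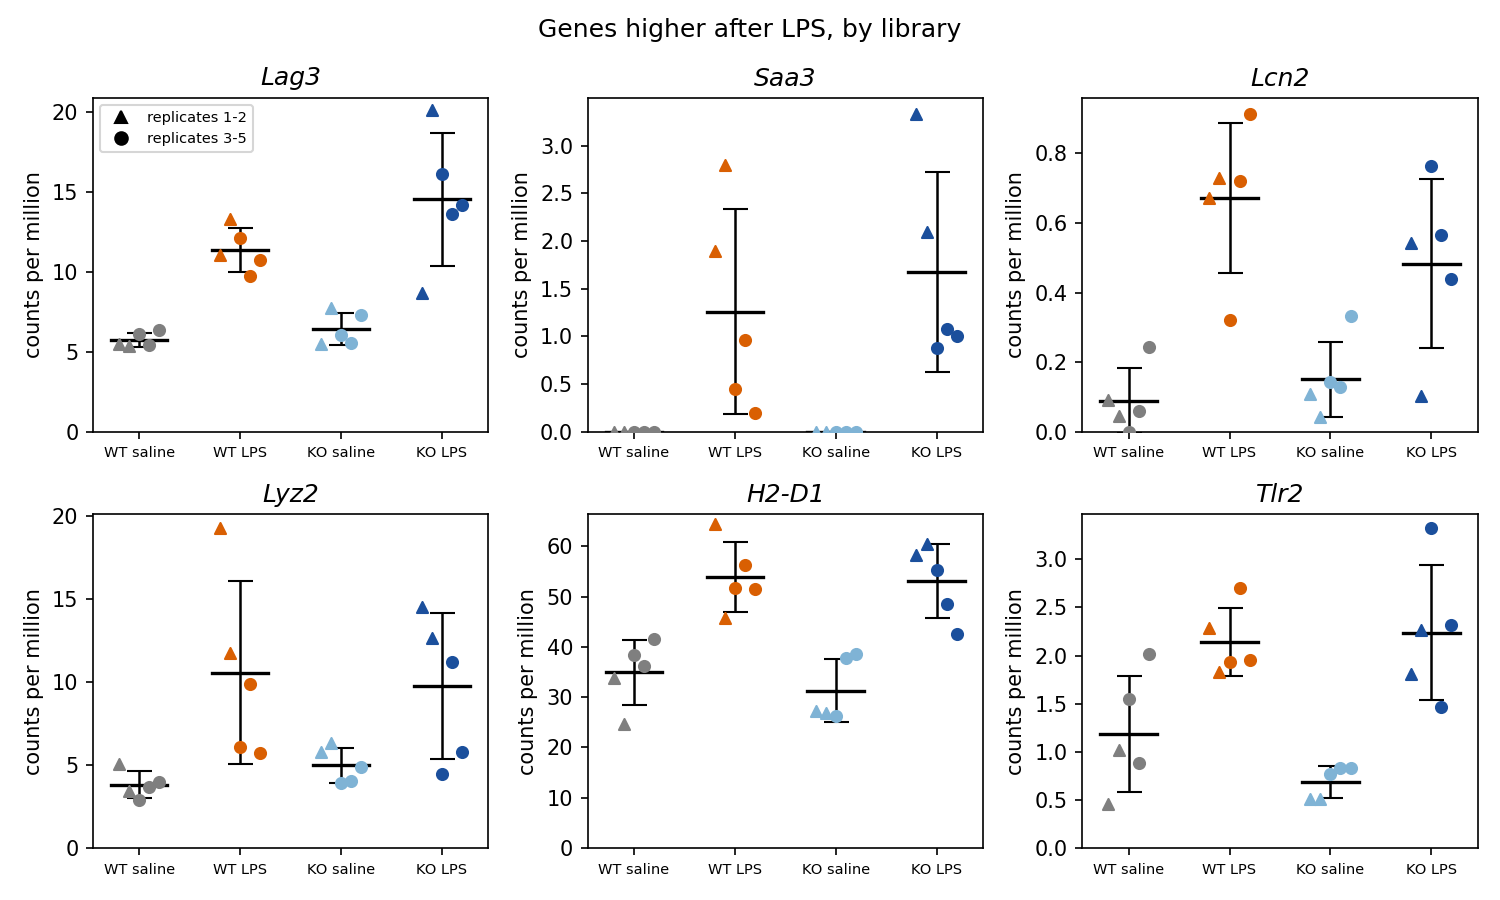
Levels (CPM, linear axes from 0) of Lag3, Saa3, Lcn2, Lyz2, H2-D1 and Tlr2 in each library by group; triangles are replicates 1 and 2, circles replicates 3 to 5, and lines the group mean with its SD (n = 5). Lag3 went from a mean of 5.74 to 11.4 CPM in wild-type and from 6.42 to 14.5 CPM in knockout.

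Genes chosen in advance for inflammation and the glucocorticoid response did not pass the adjusted threshold in any of the 5 comparisons (edgeR). Gfap, the astrocyte filament gene, stood at 408 ± 47.4, 482 ± 31.6, 474 ± 78.1 and 533 ± 39.8 CPM (SD, n = 5) in wild-type saline, wild-type LPS, knockout saline and knockout LPS. In the same order, Serpina3n had 56.5, 58.8, 61.2 and 68.4 CPM, C4b 38.3, 50.6, 44.3 and 52.2, C3 0.525, 0.857, 0.569 and 1.30, and Aif1 4.61, 4.68, 4.13 and 5.18. C4b and Aif1 lie within 20 Mb of Fkbp5. Among genes of the glucocorticoid response, the receptor Nr3c1 had 80.6, 79.0, 86.1 and 74.9 CPM, the co-chaperone Fkbp4 106, 112, 106 and 104, Tsc22d3 57.6, 61.5, 57.0 and 60.9, Sgk1 80.7, 74.3, 75.2 and 84.1, and Per1 72.4, 73.3, 71.8 and 74.1. Counts of Tnf, Il1b, Il6 and Cxcl10 were too low for these genes to be tested.

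**Figure D4:**
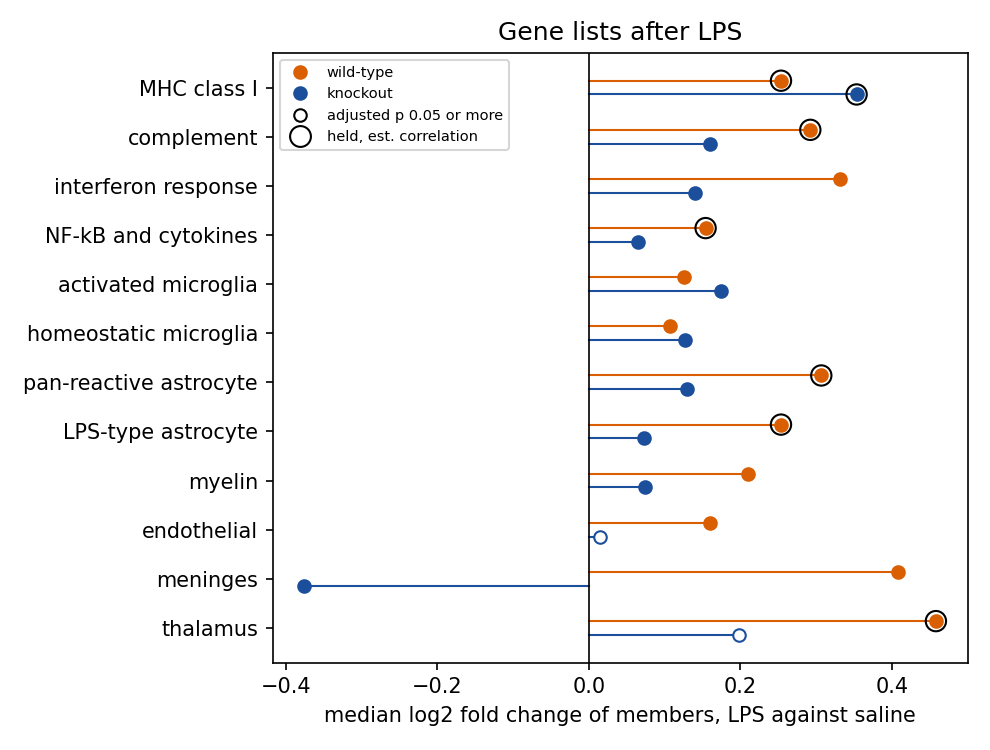
Median log2 fold change of the members of 12 gene lists, LPS against saline, with 1 point per list in wild-type and 1 in knockout; open points did not pass camera, and a ring marks calls that held with an estimated correlation. The class I antigen presentation list stands at 0.25 and 0.35, and the meningeal fibroblast list at 0.41 and -0.38.

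Knockout against wild-type after saline asked what the loss of Fkbp5 changed without inflammation. Apart from Fkbp5, Hmga1b (ENSMUSG00000078249, chromosome 11, 120762794 to 120764419) went from 0.064 to 18.3 ± 0.973 CPM (SD, n = 5; log2 fold change 8.05 ± 0.36, edgeR adjusted p = 2.43e-11). Its near-identical relative Hmga1, a chromatin protein gene within 20 Mb of Fkbp5, fell from 39.9 ± 2.53 to 17.2 ± 2.86 CPM (-1.21 ± 0.11, adjusted p = 5.03e-06). The pair share 99.81% identity, so the assignment of reads between them is uncertain. Gabra2 (ENSMUSG00000000560, chromosome 5, 70957597 to 71095849), a GABA-A receptor subunit, rose from 72.7 ± 21.3 to 262 ± 31.6 CPM (1.85 ± 0.19, adjusted p = 1.58e-05). Glo1, a detoxifying glyoxalase within 20 Mb of Fkbp5, rose from 106 ± 20.4 to 212 ± 30.1 CPM (1.00 ± 0.15, adjusted p = 0.00206). Gpnmb, a glycoprotein of phagocytes, fell from 6.61 ± 1.30 to 1.77 ± 0.46 CPM (-1.90 ± 0.24, adjusted p = 1.87e-04).

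In total 22 genes rose and 6 fell after saline (edgeR), and 438 had an unadjusted p under 0.05. DESeq2 called 47, limma-voom 362 and edgeR with the replicate block 59, 27 of the 28 among them; the sets alone gave 2 and 478. In replicates 1 and 2 and in replicates 3 to 5 the log2 fold change was 7.98 and 8.12 for Hmga1b, -1.39 and -1.10 for Hmga1, 1.64 and 2.07 for Gabra2, 1.11 and 0.96 for Glo1 and -1.98 and -1.84 for Gpnmb. All 5 passed in replicates 3 to 5, and Hmga1b alone of them in replicates 1 and 2 (adjusted p = 0.00699, the others 0.205 to 0.886). Other named genes were Zfp239 (0.72 ± 0.09, adjusted p = 1.41e-04), Dnah6 (2.34 ± 0.39, 0.00647), Zkscan1 (0.55 ± 0.10, 0.0136), and Decr2, within 20 Mb of Fkbp5 (-0.81 ± 0.10, 2.54e-04). Several calls lay close to the threshold. Zkscan1 was lost without wild-type saline replicate 4 or 5 or knockout saline replicate 3 (0.0533 to 0.0697). Hbq1a, a globin with a near copy (2.64 ± 0.49, adjusted p = 0.022), was kept only without wild-type saline replicate 4 or knockout saline replicate 1 or 2, and otherwise reached 0.0535 to 0.0966. Bend4 (adjusted p = 0.026) was kept only without wild-type saline replicate 2 or knockout saline replicate 3 or 4 (otherwise 0.0518 to 0.122). Nat8f5 (-2.21 ± 0.44, 0.043) was kept only without knockout saline replicate 4 (otherwise 0.0508 to 0.165). Dnah8 (1.90 ± 0.36, 0.0257), within 20 Mb of Fkbp5, overlaps Glo1 on the opposite strand with 26.9 against 3175 mean counts, so its value is uncertain. Its call was kept only without wild-type saline replicate 4 or knockout saline replicate 3 or 4 (otherwise 0.0615 to 0.11).

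Lists of tissue borders were higher in knockout after saline. Meningeal fibroblast markers had 12 of 13 members above 0 and a median of 0.58 (adjusted p = 2.24e-07, and 0.596 with an estimated correlation), with Slc22a6 at 1.07 and Ogn at 0.85. Choroid plexus markers had 13 of 14 above 0 and a median of 0.39 (1.84e-05, and 0.596 estimated), with Tmem72 at 2.15 and Cldn2 at 1.08. Border macrophages had 0.00541 (0.83 estimated) and pan-reactive astrocytes 0.00962 (0.596 estimated). Myelin genes were lower, with 13 of 15 below 0 and a median of -0.18 (1.91e-04, and 0.83 estimated). Glutamate synapse (higher, 0.0345), mitochondrially encoded (lower, 0.0345), HSP90 chaperone (higher, 0.0392) and class I genes (lower, 0.0392) each had 0.83 with an estimated correlation. The class I list, mostly within 20 Mb of Fkbp5, had 0.0791 with the replicate block and 0.0578 without the 3 libraries with the most thalamus RNA, and the HSP90 list 0.165 without genes near Fkbp5. These were 9 of 38 lists, with 6 and 15 in the sets alone. In replicates 1 and 2 only 2 of the 9 calls were kept, myelin (0.025) and HSP90 chaperones (7.75e-04), while meningeal markers had 0.0508 and choroid plexus 0.0791. In replicates 3 to 5, 7 of the 9 were kept, with 4.2e-06 for meningeal markers, 0.00168 for choroid plexus and 0.0333 for myelin; class I genes had 0.0519, and HSP90 chaperones 0.813 with the opposite direction. The glucocorticoid receptor targets, of which 24 were measured, did not pass the threshold (adjusted p = 0.378). Over all genes tested 1 list had a member past the threshold, Gpnmb of activated microglia, and adjusted over the list alone 5 lists had one.

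After LPS, 21 of the genes called after saline were called again between the genotypes. Hmga1b went from 0.0368 to 22.9 ± 4.44 CPM (8.94 ± 0.38, edgeR adjusted p = 8.78e-12), Hmga1 from 45.7 ± 4.90 to 18.99 ± 2.22 (-1.27 ± 0.11, 2.96e-06), Gabra2 from 56.5 ± 6.26 to 219 ± 55.2 (1.95 ± 0.19, 7.05e-06), Glo1 from 106 ± 16.3 to 207 ± 33.6 (0.97 ± 0.15, 0.00418) and Gpnmb from 5.90 ± 0.83 to 1.93 ± 0.68 (-1.63 ± 0.23, 0.00159). Tfrc, the transferrin receptor, fell from 104 to 73.8 CPM (-0.50 ± 0.09, 0.0171) and Inmt, a methyltransferase, from 1.93 to 0.248 CPM (-2.86 ± 0.51, 0.0164). In total 19 genes rose and 5 fell (537 at an unadjusted p under 0.05, DESeq2 53, limma-voom 62, replicate block 63 with 23 of the 24; the sets alone 2 and 120). In the sets the log2 fold change was 8.58 and 9.57 for Hmga1b, -1.29 and -1.25 for Hmga1, 1.85 and 2.02 for Gabra2, 0.94 and 0.97 for Glo1 and -1.85 and -1.51 for Gpnmb; all 5 passed in replicates 3 to 5, and Hmga1b alone of them in replicates 1 and 2 (adjusted p = 0.00398, the others 0.364 to 0.95). The count was 16 without wild-type LPS replicate 5. Inmt was lost without wild-type LPS replicate 5 or knockout LPS replicate 3, 4 or 5 (0.0562 to 0.0761), and Tfrc without wild-type LPS replicate 2 or 5 or knockout LPS replicate 2, 3 or 4 (0.0507 to 0.0862). Dnah6 (adjusted p = 0.0134) was lost without wild-type LPS replicate 3 or 5 or knockout LPS replicate 2 (0.0511 to 0.0576). Zkscan1 (0.0326) was kept only without wild-type LPS replicate 2 or knockout LPS replicate 1 (otherwise 0.0582 to 0.125).

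Myelin and endothelial lists were lower in knockout after LPS. Myelin genes had 14 of 15 members below 0 and a median of -0.35 (adjusted p = 3.66e-10, and 0.386 with an estimated correlation; 1.84e-06 and 4.88e-04 in the sets). Mal stood at 204 CPM in wild-type and 131 in knockout and Cldn11 at 141 and 102. Endothelial markers had 14 of 15 below 0 and a median of -0.28 (1.84e-08, and 0.386 estimated; 0.0701 and 3.97e-08 in the sets), with Vwf, which binds platelets, at -1.05 (adjusted p = 0.177, and 0.0145 with the replicate block). Interferon response genes had 17 of 23 below 0 and a median of -0.24 (0.0169, and 0.769 estimated; 0.0552 and 0.119 in the sets). Dentate granule markers (lower, 0.0162), immediate early genes (higher, 0.0138), choroid plexus (higher, 0.0334) and thalamus markers (lower, 0.0493) had 0.769 with an estimated correlation, and interneuron markers (higher, 0.0221) had 0.386. Without the 3 libraries with the most thalamus RNA the thalamus list had 0.583 and the interneuron list 0.167, and with the replicate block the choroid plexus list had 0.052. These were 8 of 38 lists, with 10 and 8 in the sets alone, but only 4 and 2 of the 8 were among them. Without the 3 libraries and with the replicate block 6 lists were called, with only 2 of the 8 among them. In replicates 3 to 5 only the myelin and endothelial calls were kept, and none of the 3 higher lists was called (immediate early genes 0.0509, interneuron 0.0642, choroid plexus 0.394). In replicates 1 and 2 the myelin, dentate granule, choroid plexus and thalamus calls were kept. The count of 8 called lists became 13, 14 and 13 without wild-type LPS replicates 2, 3 and 5, and 3 and 4 without knockout LPS replicates 4 and 5. Over all genes tested 1 list had a member past the threshold (Gpnmb), and adjusted over the list alone 5 lists had one.

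The interaction asked whether the response to LPS differed between genotypes. No single gene passed edgeR (182 at an unadjusted p under 0.05, 0 by DESeq2, 0 by limma-voom and 0 with the replicate block); the 5 smallest p belonged to AI467606, Zic2, Nid1, Gm15631 and Dusp16. Among lists, meningeal fibroblast markers had all 13 members below 0 and a median of -0.87 (adjusted p = 1.74e-12, and 0.468 with an estimated correlation). Fmod, a matrix proteoglycan, had 0.95 after LPS in wild-type and -0.96 in knockout, and Slc22a6 0.69 and -0.94. The list's adjusted p was 7.09e-08 and 1.25e-05 in the sets and 6.13e-04 without the 3 libraries with the most thalamus RNA. The interaction shares the knockout saline libraries of the comparisons above and is not independent of them. In all 13 of 38 lists differed, 2 higher and 11 lower, and 0 with an estimated correlation (smallest adjusted p = 0.468). In the sets 12 and 13 differed, with 7 of the 13 among them in each, and 7 differed without those 3 libraries. The count was 5 without wild-type LPS replicate 1, 7 without wild-type saline replicate 3 or knockout LPS replicate 2, and 8 without knockout LPS replicate 4. Class I genes had an interaction median of 0.10 (adjusted p = 0.361). Over all genes tested 0 lists had a member past the threshold (edgeR), and adjusted over the list alone 1 had one, Nid1 of the extracellular matrix.

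Across the 16419 tested genes, which are not independent replicates, the genotype changes after saline and after LPS correlated with Pearson's r = 0.509 and Spearman's rho = 0.258 (r = 0.392 and 0.45 in the sets). Without wild-type LPS replicate 1 these were r = 0.266 and rho = 0.0379. Of 31 genes called in either, 21 were called in both, all with the same sign. The LPS changes in the 2 genotypes correlated with r = 0.217 and rho = 0.0962 (r = 0.221 and 0.0797 in the sets), and r was -0.133 without wild-type LPS replicate 1. This correlation thus changed widely with 1 library left out, up to r = 0.483 without wild-type saline replicate 1. It was 0.242 without the 3 libraries with the most thalamus RNA, which include wild-type LPS replicate 1.

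Over both treatments 48 genes rose and 24 fell in knockout (edgeR; 787 at an unadjusted p under 0.05, DESeq2 127, limma-voom 536, replicate block 176 with all 72; the sets alone 8 and 1254). Their positions were uneven. Chromosome 6 held 20 of the 72, against 824 of 16419 tested genes (1-sided Fisher exact p = 2.15e-10). Within 20 Mb of Fkbp5 lay 7 of the 71 apart from Fkbp5, 9.86% against 3.22% of tested genes (1-sided Fisher exact p = 0.0077). Runs of neighbouring called genes lay on chromosome 17 from 26081208 to 30963220 (8 genes), chromosome 6 from 117862100 to 125344943 (6) and 81984321 to 86793584 (5), chromosome 5 from 64952031 to 73312560 (5) and chromosome 18 from 74440936 to 80225855 (5). Pseudogenes made up 10 of the 72 and all rose, against 2.16% of tested genes (1-sided Fisher exact p = 3.21e-06). Chosen after their values were seen, Gm13443, a near-identical pseudogene copy of Glo1, had 0.177 CPM in wild-type and 12.7 in knockout, and Gm12751, a copy of Polr1d, had no count in wild-type saline and was at least 77.5-fold higher in knockout. AC165951.1, also chosen after its values were seen and within 20 Mb of Fkbp5, went from 0.0737 to 30.2 CPM after saline.

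**Figure D5:**
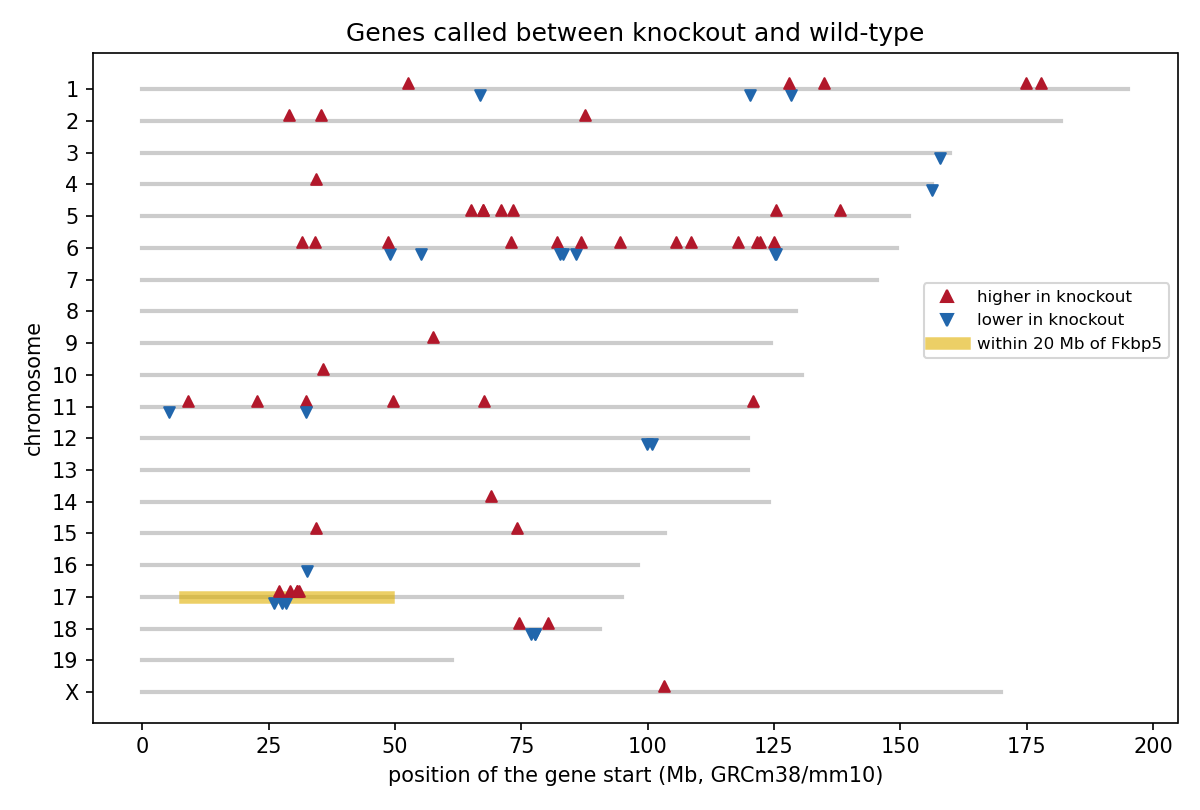
Positions (Mb, mm10) on each chromosome of the genes that differed between knockout and wild-type over both treatments; triangles pointing up are genes higher in knockout and those pointing down lower, and the yellow band marks 20 Mb around Fkbp5. Chromosome 6 holds 20 of the 72 genes, of which 1 on an unplaced contig is not drawn.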

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

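The tests on the genotype genes, on class I genes and the splits for LPS in wild-type were chosen only after the results were seen; the tests on the library sets and the other splits were chosen before.

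Genes that differed between knockout and wild-type over both treatments clustered on the genome. DNA of another strain around Fkbp5 accounts by position only for genes near it, and 64 called genes lay outside the 20 Mb window. Reads shared with a near-identical copy cannot account for all called genes, since 58 had no copy. The 64 include genes whose near-identical relative lies in the window, such as Hmga1b and Gm13443, so for these position alone does not decide. For the genes near Fkbp5 (1-sided Fisher exact p = 0.0077) and for those with a copy (1-sided Fisher exact p = 1.01e-04) these stay candidate explanations. DNA of another strain on other chromosomes is a candidate explanation for the rest: 35 of 64 lay 100 kb to 5 Mb from another called gene, against a median of 17 and a maximum of 34 in 10000 random draws (permutation p = 0.0001, the smallest they can give; with the replicate block 107 of 160 against a median of 84 and a maximum of 109, p = 0.0008), and C57BL/6J is known for an intronic deletion that lowers Gabra2 while Glo1 varies in copy number among inbred strains. An effect of FKBP5 loss through the glucocorticoid receptor stays open, since the adjusted camera p of its target list was 0.378.

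The class I antigen presentation list passed camera as higher after LPS in both genotypes. Within each genotype 0 of its members were past the threshold over all genes tested (edgeR), and 3 and 5 were when adjusted over the list alone. In the comparison over both genotypes its members H2-D1 and H2-Q6 passed over all genes tested. Without the 3 libraries with the most thalamus RNA the list was still called in wild-type (camera with the preset correlation, adjusted p = 4.64e-06). It was also called there within each library set (larger adjusted p = 1.03e-04). By that test 9 of 100 splits in wild-type, the real one included, gave as many called lists. That count covers all lists and does not single out this one. The library sets are argued against as the cause, since every group held both in the same numbers. In wild-type replicates 1 and 2 the list's mean log2 level was -0.0905 and -0.476 after saline, and 0.503 and 0.01 after LPS. In replicates 3 to 5 it was -0.084 to 0.0516 and 0.177 to 0.368. In knockout, too, every LPS library lay above every saline library of its set. The p-values alone do not settle whether neighbouring tissue accounts for the list. A lasting effect of LPS stays open as a hypothesis, and with the replicate block and an estimated correlation the list's adjusted p was 0.0688 in wild-type and 0.169 in knockout.

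Replicates 1 and 2 stood apart from replicates 3 to 5 in every group. Depth is argued against, since after thinning to equal totals the sets still differed by 2113.2 genes detected. Without the 30 mitochondrial genes 10551 genes still differed. TMM normalization already allows for a few genes that take many counts, so this removal could hardly change the number. It therefore does not decide on a few abundant genes. GC content and gene length are argued against, as the cause of the whole difference, since the larger Spearman rho across genes was -0.11, although genes higher in replicates 1 and 2 had a median exon length of 4807 bp against 3917 bp for those higher in replicates 3 to 5. No biological explanation was tested, and the labels name no batch.

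Other splits of the libraries were counted, out of 100 each. These splits ignore the replicate numbers and library sets, while the real groups are balanced over the sets, so they do not exclude chance. Few were as large for the called genes of LPS in knockout (3 splits as large, real 1, highest other 3), knockout after saline (3 splits, 28, 1210), knockout after LPS (2 splits, 24, 4254) and LPS over both genotypes (3 splits, 7, 8231). For knockout over both treatments 6 splits were as large (real 72, highest other 5758), and the other 5 of them followed the library sets. Of these 100 splits, the 27 balanced over the sets gave at most 0 genes apart from the real one (edgeR). Chance was not excluded among all splits. Among those within replicate numbers, given below, 1 of 100 was as large, and 2 of 100 with the replicate block. For LPS in wild-type (100 splits, highest other 5571) and the interaction (100 splits, highest other 2721) the real edgeR count was 0, so every split was as large by construction and the comparison decides nothing. The splits with the largest counts followed the library sets, a structure of the samples. With the replicate block the real counts were 59, 63 and 176 for the genotype comparisons. Among the 100 drawn for each comparison, those balanced over the sets gave at most 0 genes by edgeR, apart from the real split. For edgeR the unadjusted and other counts are given in the report. Splits within replicate numbers, which are balanced over the sets too, gave up to 17 genes for knockout over both treatments and 7 for the interaction. For called lists chance was not excluded for LPS in wild-type (9 splits, 21, 26), LPS in knockout (12, 17, 19), knockout after saline (62, 9, 22), knockout after LPS (77, 8, 15) or the interaction (33, 13, 25). Among splits that exchange groups within replicate numbers, 1 of 16 was as large for genes of LPS in knockout, knockout after saline and knockout after LPS, with 0 as the highest other, and 16 splits are too few for a share under 0.05. With the replicate block in the fit, 2 of 16 were as large for knockout after saline (real 59, highest other 210) and for LPS in wild-type (real 3, highest other 3), and 1 of 16 for LPS in knockout (real 5, highest other 0) and knockout after LPS (real 63, highest other 3). For LPS and for knockout averaged over the other factor, 1 of 100 such splits was as large (highest other 1 and 17), and with the block 1 and 2 of 100 (real 27 and 176, highest other 5 and 249). For lists 3, 3, 6 and 11 of 16 were as large in the order above, and 41 of 100 for the interaction.

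Single libraries stood far from the other 4 of their group in 14 of 396 groups, and chance alone gives about 1 in 20. In wild-type saline these were the mean log2 level of class I genes in replicate 2 (-0.476, others -0.0905 to 0.0516), of HSP90 chaperones in replicate 1 (-0.342, others 0.0229 to 0.101) and of extracellular matrix in replicate 1 (0.408, others -0.285 to -0.113). In the same group, in CPM, they were Hbq1a in replicate 4 (0.592, others 0.213 to 0.306), Ogn in replicate 5 (6.85, others 4.39 to 4.97), Serpina3n in replicate 1 (52, others 57 to 58.6) and Zic2 in replicate 2 (7.52, others 10.2 to 11.2). In wild-type LPS, Mal was 322 CPM in replicate 2 (others 161 to 192) and Nr3c1 53.3 in replicate 1 (others 83.2 to 89.4). In knockout saline, Cdh5 was 8.27 CPM in replicate 3 (others 10.8 to 11.8) and Dnah6 7.6 in replicate 1 (others 4.22 to 4.94). In knockout LPS, neurogenesis genes scored -0.363 in replicate 2 (others -0.129 to -0.0773), extracellular matrix 0.45 in replicate 1 (others -0.205 to -0.0217), and Bend4 was 15.3 CPM in replicate 2 (others 12.2 to 12.8).

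For 13 lists the interaction test in camera with a preset correlation gave an adjusted p under 0.05. With an estimated correlation 0 of 38 did, and 33 of 100 splits of the libraries gave as many lists, so chance was not excluded. The change after LPS was lower in knockout than in wild-type for meningeal fibroblasts (adjusted p = 1.74e-12), homeostatic astrocytes (0.000621), border macrophages (0.00119), endothelial markers (0.00119), thalamus (0.00494), extracellular matrix (0.00522), dentate granule cells (0.0055), mural cells (0.00951), interferon response (0.03), pan-reactive astrocytes (0.0493) and myelin (0.0493). It was higher in knockout for nuclear oxidative phosphorylation genes (0.0478) and interneuron markers (0.0493). With an estimated correlation the adjusted p of these 13 ran from 0.468 to 0.739. With the replicate block the calls ended for interferon response (0.0509), myelin (0.0551) and pan-reactive astrocytes (0.0893). Without the 3 libraries with the most thalamus RNA they ended for border macrophages (0.254), thalamus (0.293), extracellular matrix (0.0513), interferon response (0.0513), pan-reactive astrocytes (0.154) and interneuron markers (0.186).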

How the results depend on the processing

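The alternatives named as planned were chosen before the data were examined; the library set term, the sets alone, the fits without the 3 libraries with the most thalamus RNA, and the block with an estimated correlation were chosen only after the results were seen. Of 8790 alternative values for named genes, 106 were no longer past their threshold and 59 were newly past it. Only values of the 26 calls in the fit without further terms could be lost, so 8790 is not the base for losses. With 1 library left out 61 of the 106 were lost. Of all 9186 alternative values 1 was scored as reversed, the correlation of LPS changes without wild-type LPS replicate 1. A gene's change of sign was scored so only if the gene was called in either fit. Uncalled named genes changed sign in 71 values with 1 library left out and in 29 in replicates 1 and 2 alone, among others. Lists were scored by their counts, not by their directions. All 26 calls of named genes were kept under DESeq2's size factors, DESeq2, limma-voom, the replicate block, the surrogate variable, the set term and replicates 3 to 5 alone, 21 without a filter, 17 with only the 2 groups compared, 21 without the 3 libraries and 2 in replicates 1 and 2 alone. With the replicate block these lists were newly called: for LPS in wild-type CA1 neurons (adjusted p = 0.0246), cortex (0.0196), cholesterol synthesis (0.00714) and oxidative phosphorylation (0.00907), for LPS in knockout mitochondrially encoded genes (0.0375), for knockout after saline homeostatic microglia (0.0173), homeostatic astrocytes (0.0186), cholesterol synthesis (0.0473) and ribosomal proteins (0.0473), for knockout after LPS homeostatic astrocytes (0.00867), mitochondrially encoded genes (0.0412) and oxidative phosphorylation (0.0412), and for the interaction circadian genes (0.0156) and ribosomal proteins (0.000467). Apart from these and the values with the block given elsewhere in the text, the block changed no call of a list, nor of a gene in a comparison for which the rule named it. The mean log2 level of the CA1 list was -1.04 in wild-type LPS replicate 1. It was -0.104 to 0.334 in the other wild-type LPS libraries and -0.167 to 0.236 in wild-type saline. Knockout LPS replicate 1 had -0.956. Of the 3 libraries with the most thalamus RNA, these 2 were low in CA1 markers, and wild-type LPS replicate 4 had 0.0398. Where values below moved, the cause was not tested, except that fewer libraries give less power.

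Counts of called genes are given in the order LPS in wild-type (0), LPS in knockout (1), knockout after saline (28), knockout after LPS (24), LPS over both genotypes (7) and knockout over both treatments (72). DESeq2 gave 2, 7, 47, 53, 23 and 127. With limma-voom they were 3, 2, 362, 62, 17 and 536, with the replicate block 3, 5, 59, 63, 27 and 176, with 1 surrogate variable 3, 7, 61, 56, 25 and 227, and with the set term 3, 7, 47, 54, 24 and 152. Only the 2 groups compared gave 0 for LPS in knockout. Replicates 1 and 2 alone gave 0 for LPS in knockout, 2 after saline, 2 after LPS, 0 for LPS over both genotypes and 8 for knockout over both treatments; replicates 3 to 5 alone gave 3 for LPS in knockout and 478, 120 and 1254 for the genotype comparisons. Without the 3 libraries LPS in wild-type had 1 and LPS over both genotypes 1. With the block added to that, LPS in wild-type had 1, LPS in knockout 2, knockout after saline 53, LPS over both genotypes 4 and knockout over both treatments 123. Interaction counts were 0 under each of these edgeR, DESeq2 and limma-voom alternatives (182 genes at an unadjusted p under 0.05 in edgeR).

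Called lists (21, 17, 9, 8 and 13, the interaction last) were 6, 1, 0, 0 and 0 with an estimated correlation, and 0 in all 5 comparisons with the block and an estimated correlation (camera; smallest adjusted p 0.0631, 0.169, 0.83, 0.72 and 0.275). Replicates 3 to 5 alone gave 11 for LPS in knockout and 15 for knockout after saline. Without the 3 libraries LPS in wild-type had 13 and the interaction 7. With the replicate block added to that, the 5 counts were 20, 12, 11, 6 and 9. Fkbp5 over both treatments was -1.06 in replicates 1 and 2 alone (adjusted p = 0.12). The correlation of LPS changes was 0.0797 in replicates 3 to 5 alone, and that of genotype changes 0.392 in replicates 1 and 2 alone and 0.604 without the 3 libraries.

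Leaving out 1 library at a time, Fkbp5 ran from -1.14 to -1.08. Gene counts ran from 0 to 0 for LPS in wild-type and for the interaction, 0 to 1 for LPS in knockout, 19 to 29 for knockout after saline, 16 to 30 for knockout after LPS, 4 to 9 for LPS over both genotypes and 53 to 81 for knockout over both treatments. The count of 4 came without wild-type saline replicate 2, 3 or 4, wild-type LPS replicate 3, 4 or 5, knockout saline replicate 3 or 4, or knockout LPS replicate 1. List counts ran from 17 to 23 for LPS in wild-type, 10 (without knockout saline replicate 1; 11 without replicate 2) to 17 for LPS in knockout, 6 (without knockout saline replicate 1) to 13 for knockout after saline, 3 to 14 for knockout after LPS and 5 to 18 for the interaction. The correlation of genotype changes ran from 0.266 (without wild-type LPS replicate 1) to 0.65, and that of LPS changes reversed to -0.133 without wild-type LPS replicate 1 and reached 0.483 without wild-type saline replicate 1. Saa3 had 143 and 204 counts over the LPS groups; whether more depth would change its call was not tested.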

Other observations

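The sums over gene pairs were computed only after the results were seen. Counts of Hmga1 and Hmga1b moved in opposite directions between the genotypes while their sum moved little. The pair summed to 42.85 ± 4.76 CPM (SD, n = 10) in wild-type and 38.7 ± 5.34 in knockout, a log2 ratio of -0.147. Hmga1b lies on chromosome 11 and Hmga1 on chromosome 17, and the pair share 99.81% identity over 98.2% of Hmga1b.

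Hba-a2, a haemoglobin gene with a near-identical copy in Hba-a1, had a log2 fold change between knockout and wild-type of -3.36 after saline and -4.31 after LPS (edgeR adjusted p = 1 and 0.294) and passed over both treatments (-3.84 ± 0.81, adjusted p = 0.0367), while Hba-a1 stood at 11.7 CPM in wild-type and 17.01 in knockout. The sum of the pair was 13.76 ± 14.96 CPM (SD, n = 10) and 17.12 ± 15.98, a difference within the spread. C1ql2, a synaptic organizer of dentate granule cells, had -0.99 after saline and -0.997 after LPS and passed the threshold adjusted over the list alone (over all genes tested edgeR adjusted p = 0.242 after saline and 0.229 after LPS, the latter 0.0496 with the replicate block). Among the 216 genes covered by the rule, 79 overlap another gene and 31 overlap one with at least 10% of their counts, and 27 have a near-identical copy.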
